A study of Gossypium hirsutum with 12 samples.

How the data were processed

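RNA from the third youngest fully expanded leaf of cotton plants was extracted with a hot borate method, labelled with biotin and hybridised to Affymetrix Cotton arrays, per the labels' protocols. The values are MAS5 signals, per the submitters' processing notes, which give no version. The deposited values are intensity values on a linear scale, 1 per probe set and array, and the authors' table covers 24132 probe sets on 12 arrays. A trimmed mean over the 2nd to the 98th percentile of 500 on every array shows that each array had been scaled to the same target. Whether further steps were applied is not given in the sources used here. The table has no detection calls. The values of 1 array, Sicala 45 at 42 °C replicate 3, are stored with 4 decimals where the other arrays have fewer, and its lowest value is 1.09. Arrays were matched to 4 groups of 3 by their titles, and no 2 arrays held identical values.

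From these values, log2(signal + 16) was computed, with no further normalization. The pseudocount keeps dim values from spreading and makes fold changes, which are all on this scale, understate the change of dim probe sets. The 103 AFFX control probe sets were left out, as were the dimmest 30% of the rest by mean over all arrays, which left 16820. A linear model of the 4 groups over all 12 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The comparisons were 42 against 32 °C in each cultivar and averaged over both, Sicot 53 against Sicala 45 at each temperature, and the difference between the heat changes. Errors of log2 changes are standard errors of the model, and errors of signals are SDs over 3 arrays. Control measures were compared with an exact permutation test within cultivars. On simulated data, with 200 of 16820 probe sets changed 4-fold, the model recovered 87.5% for heat in Sicala 45, 83% for heat in Sicot 53, 96.5% for averaged heat, 80.5% and 82.5% for the cultivar differences at 32 and 42 °C, and 51% for the difference between heat changes. For 2-fold changes it recovered 42% for averaged heat and 2.5% or less for every other comparison. The simulated noise was normal and independent between probe sets, while the arrays show variation shared across probe sets. The number of changed probe sets also moves the adjusted threshold. These shares are therefore a rough guide to the real data.

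Gene names came from the probe annotation and a gene table of assembly Gossypium_hirsutum_v2.1, matched by gene ID. Of all probe sets, 697 have 1 gene symbol, all of which matched, 46 have several and 23389 have none listed. A gene name was held for 318 of the 697, and 6 names of markers or clones were set aside. Among tested probe sets 258 have a name, for 207 names. Cotton is tetraploid, and probe sets whose IDs end in _s_at, _x_at or _a_at can match several related transcripts, so signal from gene copies may not be separate. No coordinates are given. The 46 gene lists were fixed as name patterns before the data were examined, and 24 of them matched no tested probe set, 18 matched 1 to 4 and 4 were tested with camera (preset correlation 0.01, and an estimated correlation as an alternative) and fry. Some matches by name are ambiguous: GID1 matched the clock list as well as the gibberellin list.

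Also before the data were examined, a rule fixed the genes to name: of called probe sets with 1 informative gene name whose groups did not overlap, the 12 largest rises and falls for averaged heat and the 10 largest for each other comparison, with 1 probe set per name, the one of lowest p. Added to these were up to 4 list members of lowest p, any Rubisco activase and up to 2 unnamed probe sets per direction. The alternatives planned then were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a filter at 50%, eBayes without the trend, array weights, a fit of only the groups compared, the replicate number as a block, and leaving out each array. Added after the data were seen were scaling to the poly-A spikes, the mean 3'/5' ratio of actin and ubq11 as a covariate, and leaving out the 2 arrays with a ubq11 ratio above 20. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.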

Results

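Leaf transcript levels of upland cotton (Gossypium hirsutum) were measured on 12 Affymetrix Cotton arrays, which form 4 groups of 3. The plants were of 2 cultivars, Sicala 45 and Sicot 53, held in a growth cabinet at 32 °C by day or at 42 °C by day, with nights of 25 °C at the higher setting. Plants had 4 d to settle at 32 °C by day and 25 °C by night before the treatment began. The sampled organ was the third youngest fully expanded leaf. By its title, the series asks what molecular events lie behind the way cultivars differ in physiology and in tolerance of heat. The 42 °C plants entered the cabinet after the 32 °C plants had left it, so temperature cannot be told apart from cabinet run in any comparison of temperatures. The labels name 3 leaf tissue samples per group and do not say whether they came from separate plants, so p-values measure the spread between these samples. The deposited MAS5 signals cover 24132 probe sets per array, with a trimmed mean of 500 on every array and medians between 86.4 and 115. Within groups, log2 values of 2 arrays correlated across probe sets at r between 0.914 and 0.968. With 3 arrays per group, the number of arrays limits the precision.

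Control probe sets differed between the temperatures. The poly-A spikes (dap, lys, phe and thr), bacterial transcripts added to the sample RNA before labelling, gave 1.45 times the signal at 42 °C (log2 change +0.53 ± 0.13 SE, 6 arrays against 6, exact two-sided permutation test within cultivars over 400 arrangements, p = 0.01). The ratio of the 3' to the 5' probe set of the cotton ubiquitin gene ubq11, which rises as RNA or cDNA loses its 5' part, was 2.25 times as high (log2 change +1.17 ± 0.48 SE, exact permutation p = 0.02). Its values were 4.73 to 10.7 on the 32 °C arrays and 6.39 to 41.5 on the 42 °C arrays. The same ratio for actin was 1.01 times as high (log2 change +0.02 ± 0.32 SE, exact permutation p = 0.925). The ubq11 3' signal was itself higher at 42 °C (log2 change +0.82 ± 0.19 SE, exact permutation p = 0.005). The ratio rose by more than the 3' signal, so the 3' rise does not account for all of it. On average the 5' signal was therefore lower at 42 °C, a change that was not tested on its own. A loss of the 5' part stays open, as the actin ratio showed no such rise.

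**Figure D1:**
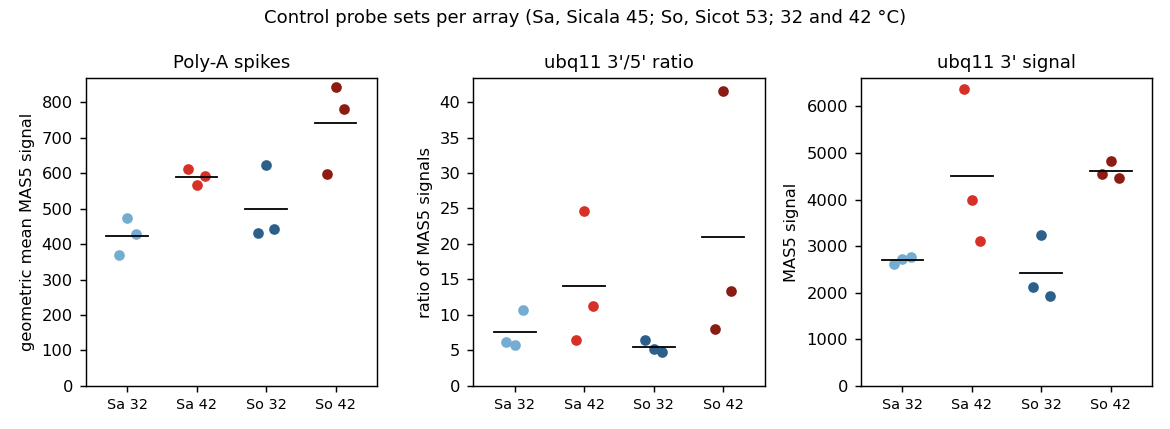
Signals of control probe sets on each of the 12 arrays, by cultivar and temperature: the geometric mean MAS5 signal of the poly-A spikes, the ubq11 3'/5' ratio and the ubq11 3' signal, with a line at each group's mean of 3 arrays. Spike signals lay between 369 and 622 at 32 °C and between 567 and 844 at 42 °C, and the largest ubq11 ratio was 41.5.

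The first comparison asks which transcripts differed between 42 °C and 32 °C, averaged over both cultivars. Of the named genes whose arrays did not overlap between temperatures in either cultivar, NAC4 and RAV1 had the largest rises. NAC4 (LOC107916546), a NAC-domain transcription factor, rose 10.1-fold (log2 change +3.33 ± 0.23 SE, limma adjusted p = 2.08e-05), from a mean signal of 151 ± 34.7 (SD, n = 3) to 1760 ± 461 in Sicala 45 and from 148 ± 62.6 to 1550 ± 485 in Sicot 53. RAV1 (LOC107946446), a factor with AP2 and B3 DNA-binding domains, rose 5.42-fold (+2.44 ± 0.38), NAC2 (LOC107962533) 2.34-fold (+1.23 ± 0.17) and the C-repeat binding factor CBF17 (LOC107913841) 2.03-fold (+1.02 ± 0.18). ACO1 (LOC107905899), an ACC oxidase of the last step of ethylene synthesis, rose 1.92-fold (+0.94 ± 0.23), and MADS-3 (LOC107925198), a MADS-box factor, 1.66-fold (+0.73 ± 0.18). Both NAC4 probe sets, both NAC2 probe sets and all 3 RAV1 probe sets passed the threshold upward. Another probe set named CBF17 did not (log2 change +0.18, adjusted p = 0.469), and a probe set of another locus named ACO1 had a log2 change of -0.93 (adjusted p = 0.247).

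GRPL1 (LOC107953490) fell 2.52-fold (log2 change -1.33 ± 0.25 SE, limma adjusted p = 0.00814), and all 3 of its probe sets passed the threshold downward. GST (LOC107948407), a glutathione S-transferase, fell 2.24-fold (-1.16 ± 0.27), while the other 2 probe sets of that name had log2 changes of -0.15 and -0.37 and did not pass. PAP10 (LOC107908811) fell 2.24-fold (-1.16 ± 0.28), ASP3 (LOC107901245) 2.21-fold (-1.15 ± 0.25) and the class III peroxidase pod1 (LOC107945392) 2.07-fold (-1.05 ± 0.26). PK1 (LOC107946568) fell 1.77-fold (-0.82 ± 0.17), Rab7 (LOC107913905), a small GTPase of vacuolar trafficking, 1.70-fold (-0.77 ± 0.18), and SMT2-2 (LOC107905551), a sterol methyltransferase, 1.69-fold (-0.76 ± 0.21). ARF1 (LOC107914201) fell 1.63-fold (-0.70 ± 0.17) and CAP (LOC107894227) 1.61-fold (-0.69 ± 0.18). For each of these 16 genes, as the rule for naming them asked, the 3 arrays at 42 °C lay on one side of the 3 arrays at 32 °C in both cultivars. In all, 26 named genes passed the threshold, 9 higher and 17 lower at 42 °C. Leaving out each of the 12 arrays in turn kept the calls of NAC4, RAV1, NAC2, CBF17, GRPL1 and PK1. The call of ASP3 ended without Sicala 45 at 32 °C replicate 1 (log2 change -1.02), that of Rab7 without that array (-0.73) or replicate 2 of its group (-0.75), and that of GST without Sicot 53 at 32 °C replicate 1 (-1.06) or at 42 °C replicate 3 (-1.07). Others ended without any 1 of 4 (ARF1), 5 (PAP10), 6 (ACO1), 7 (pod1), 8 (MADS-3), 9 (CAP) or 10 (SMT2-2) of the arrays, with adjusted p at most 0.106.

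**Figure D2:**
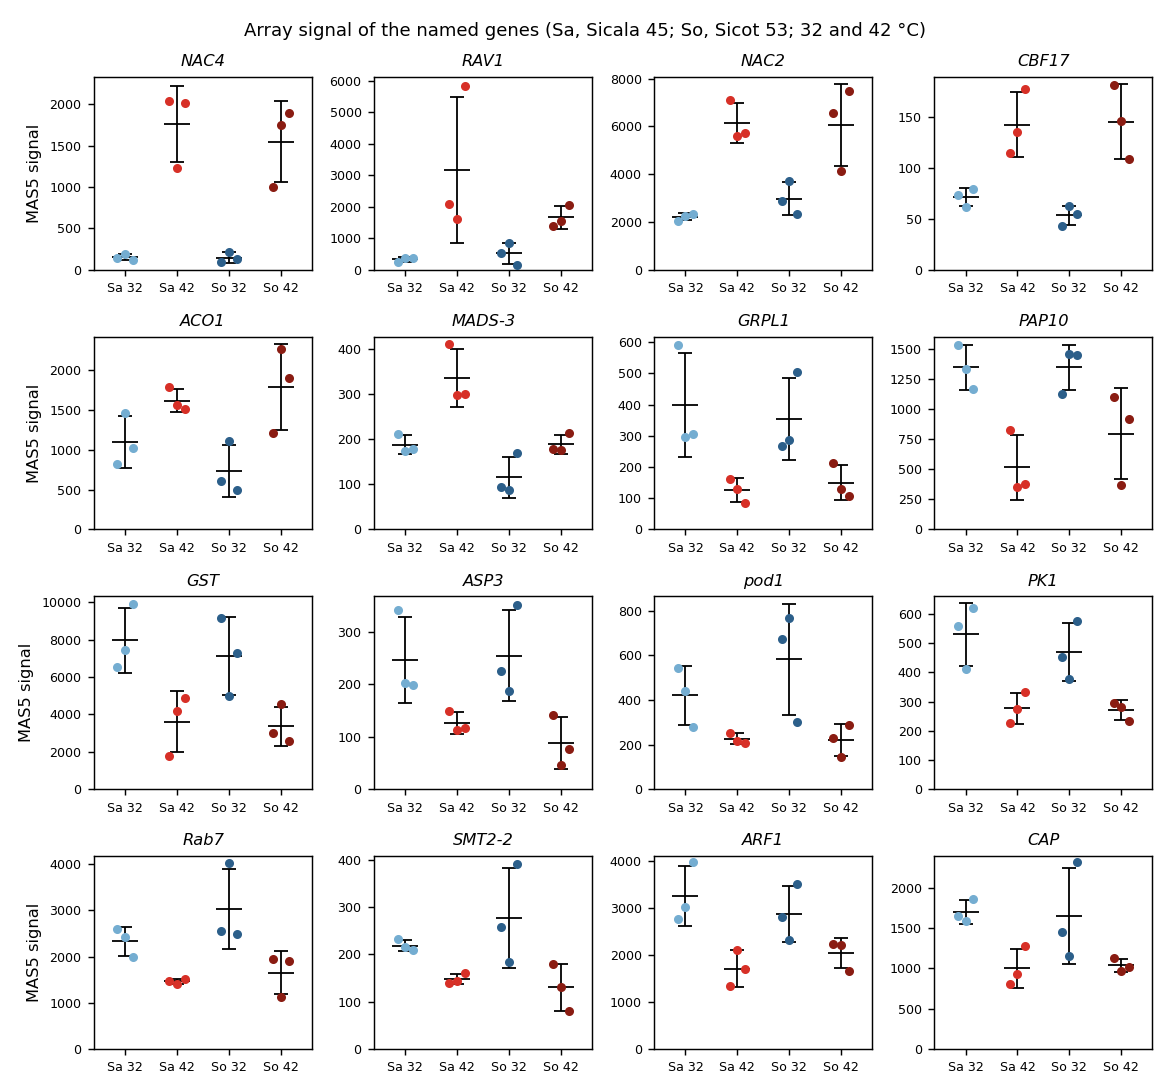
MAS5 signal of the 16 named genes whose arrays did not overlap between temperatures, with 1 point per array and the mean ± SD of 3 arrays as bars, for Sicala 45 (Sa) and Sicot 53 (So) at 32 and 42 °C. NAC4 had means of 151 and 148 at 32 °C and of 1760 and 1550 at 42 °C.

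Most probe sets carry no gene name here, including those with the largest changes. On the scale of log2(signal + 16), the unnamed probe set with the largest rise rose 87.2-fold (log2 change +6.45 ± 0.42 SE, adjusted p = 1.88e-05) from mean signals of 51.4 and 48.2 in the cultivars at 32 °C, below the median of 100 of all values. The next rose 50.9-fold (+5.67 ± 0.60) from dimmer signals of 6.32 and 18. With a pseudocount of 1 the order turned, at +6.97 and +7.25. The 2 with the largest falls both fell 12.3-fold (-3.63 ± 0.25 and -3.62 ± 0.25).

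Rubisco activase, which keeps the carbon-fixing enzyme Rubisco active, had signals near the top of the range. On each array RCA1 lay between 82.4% and 89.5% of the array's highest value, and its values went with that ceiling, so they say little about its transcript level. It had a log2 change of +0.12 ± 0.20 SE averaged over cultivars (adjusted p = 0.767), +0.32 ± 0.28 in Sicala 45 and -0.09 ± 0.28 in Sicot 53, at mean signals of 30400 ± 9940 to 40400 ± 9370 (SD, n = 3) in the groups. The highest values themselves had changes of +0.13, +0.31 and -0.06. The sign of the averaged RCA1 value turned under quantile normalization (-0.04) and under scaling to the spikes (-0.41).

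Of the 46 gene lists, 24 had no named probe set among those tested, 18 had 1 to 4 and 4 had the 5 needed for a test. The lists for small heat shock proteins, the HSP70 and HSP90 families, heat shock transcription factors, light harvesting and photosystems were among those with none and were not analysed here. Of the 8 ethylene probe sets, 1 rose over all genes tested (ACO1) and 4 passed when adjusted over the list alone. The others of the lowest p were ACO3 (log2 change +0.60 ± 0.20 SE, adjusted p = 0.0871), the ethylene response factor ERF8 (+1.16 ± 0.41, adjusted p = 0.103) and ACS1 (-0.40 ± 0.15, adjusted p = 0.116). ACS1 was matched by its name alone, so its place in the ethylene list is uncertain. The list showed no shift against other genes (camera adjusted p = 0.902), with a median of -0.27 and a mean of +0.06, and fry's test for change in either direction gave an adjusted p of 0.000445. Of 5 class III peroxidases, pod1 fell and pod5 had +1.05 ± 0.33 (adjusted p = 0.072), and 2 passed when adjusted over the list alone (median +0.04, mean -0.01). Of 24 cell wall probe sets, 1 rose, the xyloglucan endotransglucosylase XTH3 (+1.70 ± 0.47, adjusted p = 0.0455), and 0 passed when adjusted over the list alone. The XTH3 call ended without any 1 of 9 arrays (adjusted p at most 0.107). Both the median (-0.05) and the mean (-0.03) of the list were negative, while camera's direction was up. FLA7, a fasciclin-like protein of that list, had -0.59 ± 0.33. None of the 11 lipid probe sets passed, with the desaturases 3FAD at -0.30 ± 0.19 and sad1 at -0.32 ± 0.22. Camera adjusted p-values were 0.902 for all 4 lists.

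Lists of under 5 probe sets were described without a test of the list. All 4 flavonoid genes had negative values under every scaling run, and 0 passed over all genes tested, with 1 passing when adjusted over the list alone. Dihydroflavonol reductase DFR had a log2 change of -2.57 ± 0.79 SE (adjusted p = 0.0648), and the chalcone synthases CHS6, CHS3 and CHS2 had -1.22 ± 0.55, -0.82 ± 0.52 and -0.64 ± 0.34. In the list of cotton fibre genes, markers of another cell type, Fb2 had -0.69 ± 0.21 (adjusted p = 0.0607) and E6 +0.21 ± 0.21, and 1 of the 2 passed when adjusted over the list alone. GST of the glutathione S-transferase list and ARF1 of the auxin list fell, as given above, each the 1 call among 3 probe sets. ARF1 is also a name of ADP-ribosylation factors, so its place in the auxin list is uncertain. The other auxin probe sets are named FSLTP2, which the lipid list also holds, so the list may contain no auxin gene. The other lists with a named probe set had 0 calls. Among them, the glycolate oxidase GOX of photorespiration had +0.27 ± 0.20, the superoxide dismutase CSD2a +0.27 ± 0.14, the catalase CAT2 -0.12 ± 0.21, CLP +0.24 ± 0.23, and the late embryogenesis genes Lea14-A and Lea5-D +0.51 ± 0.25 and +0.73 ± 0.80.

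Over all genes, 1481 of 16820 tested probe sets passed the threshold for averaged heat (limma, Benjamini-Hochberg adjusted p under 0.05), 709 higher and 772 lower, and 648 of them changed at least 2-fold. Scaling each array to its spikes, chosen after the data were seen, gave 269 higher and 5596 lower, with a median change of all tested probe sets of -0.53 in place of -0.05. Under that scaling all 10 named falls kept their calls, while CBF17 (+0.57), ACO1 (+0.42) and MADS-3 (+0.24) no longer passed, and DFR (-3.09), CHS6 (-1.59), CHS2 (-0.99), 3FAD (-0.79), sad1 (-0.84), FLA7 (-1.09), ACS1 (-0.93), CAT2 (-0.65) and Fb2 (-1.20) did. Median centring gave 776 higher and 434 lower, and array weights 1250 higher and 1704 lower. Without the 2 arrays with a ubq11 ratio above 20, replicate 2 at 42 °C of each cultivar, also left out only after the data were seen, 783 probe sets passed. Leaving out Sicala 45 at 32 °C replicate 1 gave 763 and replicate 2 gave 928, and leaving out Sicot 53 at 32 °C replicate 1 gave 807, at 42 °C replicate 2 gave 899 and replicate 3 gave 837.

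Within Sicala 45, NAC4 rose 10.5-fold at 42 °C (log2 change +3.39 ± 0.33 SE, limma adjusted p = 0.000839), RAV1 7.93-fold (+2.99 ± 0.54, adjusted p = 0.0171) and NAC2 2.74-fold (+1.45 ± 0.24, adjusted p = 0.0116). GRPL1 fell 4.59-fold (-2.20 ± 0.34, adjusted p = 0.00901) and APY1, an apyrase, 2.85-fold (-1.51 ± 0.30, adjusted p = 0.0236). Within Sicot 53, NAC4 rose 9.65-fold (+3.27 ± 0.33, adjusted p = 0.00209) and CBF17 2.30-fold (+1.20 ± 0.26, adjusted p = 0.047), and GRPL1, on another of its probe sets, fell 2.13-fold (-1.09 ± 0.24, adjusted p = 0.047). In each of these changes, as the rule for naming them asked, the 3 arrays at 42 °C lay apart from the 3 at 32 °C. Outside the cultivar of their call, RAV1 had +1.89 (limma adjusted p = 0.127), NAC2 +1 (0.0765) and APY1 -0.71 (0.284) in Sicot 53, and CBF17 had +0.84 (0.139) in Sicala 45. These had the same sign in both cultivars, and none passed the test of a cultivar difference in heat change. Neither GRPL1 probe set passed in the other cultivar either. The one called in Sicala 45 had -0.69 in Sicot 53 (limma adjusted p = 0.357), and the one called in Sicot 53 had -0.40 in Sicala 45 (adjusted p = 0.457). Omitting single arrays ended the Sicala 45 calls of RAV1 (each 32 °C replicate of that cultivar, adjusted p at most 0.0824), NAC2 (its 32 °C replicates 1 and 2, at most 0.0583) and APY1 (any 1 of 5 arrays, at most 0.118), and in Sicot 53 those of CBF17 (any 1 of 10, at most 0.196) and GRPL1 (any 1 of 9, at most 0.18). In Sicala 45, 304 probe sets passed the threshold, 193 higher and 111 lower, and in Sicot 53 228 passed, 177 higher and 51 lower. None of the 4 tested lists passed camera in either cultivar (adjusted p at least 0.826). Fry's test for change in either direction gave the ethylene list an adjusted p of 0.0248 in Sicala 45 and 0.212 in Sicot 53, and the other lists did not pass it. Within 3 arrays against 3, chance parts the groups at 10% of probe sets, and they were apart at 3465 of 16820 in Sicala 45 and 3510 in Sicot 53.

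These counts depended on single arrays. Leaving out Sicala 45 at 32 °C replicate 1, 2 or 3 gave 105, 98 or 128 probe sets for Sicala 45, and leaving out its 42 °C replicate 1 gave 166. For Sicot 53, leaving out the 32 °C replicate 1 or 3 gave 18 or 50, and the 42 °C replicate 2 or 3 gave 66 or 87. Without the 2 arrays with high ubq11 ratios, 218 and 15 passed. Scaling to the spikes gave 89 higher and 413 lower in Sicala 45 and 74 higher and 548 lower in Sicot 53. Median centring gave 188 higher and 16 lower in Sicot 53, where it moved the median change from -0.08 to +0.07. Array weights gave 274 higher and 239 lower in Sicala 45, and 885 higher and 1115 lower in Sicot 53, where the balance turned.

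The next comparison asks whether the cultivars differed in their change with heat. No probe set passed the test of that difference in limma (0 of 16820, with 321 at an unadjusted p under 0.05, where chance gives 841). Of the 32 named probe sets called for averaged heat, a GRPL1 probe set came nearest, with an adjusted p of 0.292 over these. Leaving out Sicala 45 at 42 °C replicate 3 gave 1 probe set. None of the 4 lists passed (camera adjusted p at least 0.408). The probe sets past the threshold in either cultivar, 378, had the same sign in the other in 375 cases. An exception was the unnamed probe set with the largest fall in Sicala 45 (log2 change -5.28 ± 1.21 SE, limma adjusted p = 0.0496). Its mean signal rose from 5210 to 8750 in Sicot 53. In Sicala 45 at 42 °C its values were uneven, at 4.23, 35.6 and 2140, and leaving out any 1 of 11 arrays ended its call. In both cultivars, 154 passed, 128 higher and 26 lower, where independent lists give 2.03 and 0.337. The heat changes correlated across all tested probe sets at r = 0.693 (Spearman's rho = 0.587), a description across genes, which are not independent replicates. Over the 1481 probe sets called for averaged heat, the median change in their direction was 0.936 log2 units in Sicala 45 and 0.905 in Sicot 53. The 95% interval of a single difference had a median half-width of 0.835 log2 units and excluded a difference of 1 log2 unit at 564 of them. On simulated data, the test of the difference recovered 0% of 2-fold and 51% of 4-fold differences, so most differences of 2-fold and many of 4-fold would not be detected with 3 arrays per group.

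**Figure D3:**
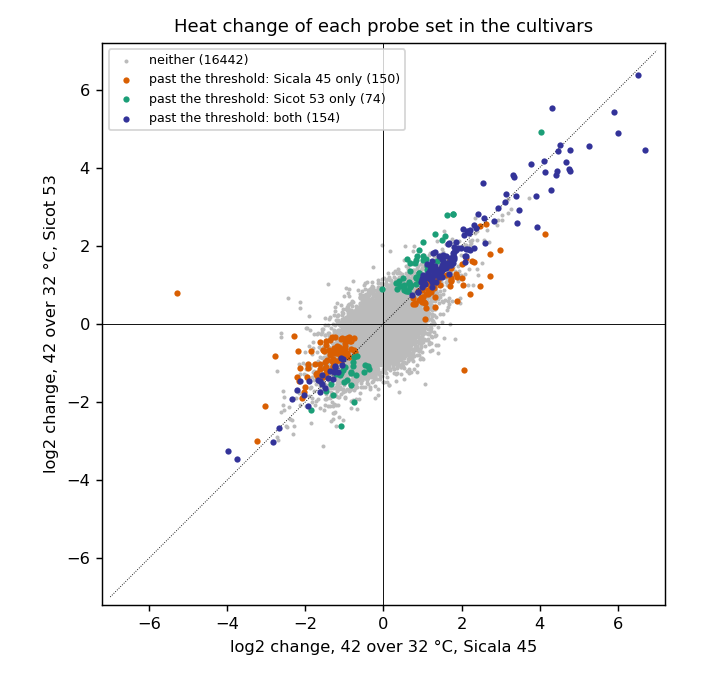
Log2 change from 32 to 42 °C of each of the 16820 tested probe sets in Sicala 45 (x axis) and Sicot 53 (y axis), coloured by whether it passed the threshold in 1 cultivar, both or neither, with a dotted line of equal change. The 154 probe sets past the threshold in both cultivars changed in the same direction.

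The last comparisons set Sicot 53 against Sicala 45 at each temperature. Few probe sets passed the threshold, and none of them has a gene name here. On simulated data, 0% of 2-fold cultivar differences were recovered at either temperature, and 80.5% and 82.5% of 4-fold differences at 32 and 42 °C. Most 2-fold differences would therefore be missed, though a called probe set differed 2.13-fold at 32 °C. At 32 °C, 18 probe sets passed the threshold (limma), 9 higher and 9 lower in Sicot 53, and at 42 °C 18 passed, 10 higher and 8 lower, all of at least 2-fold. The probe set with the largest positive difference was 29.8-fold higher in Sicot 53 at 32 °C (log2 difference +4.90 ± 0.33 SE, adjusted p = 1.8e-05) and 35.2-fold higher at 42 °C (+5.14 ± 0.33). The next was 24-fold and 28.9-fold higher (+4.58 ± 0.45 and +4.85 ± 0.45). In Sicala 45 the first had mean signals of 7.56 and 4.8 and the next 32.6 and 30.4, and with a pseudocount of 64 their order turned at both temperatures (+3.49 and +3.73 at 42 °C). The probe set with the largest negative difference was 37.1-fold and 46.6-fold lower in Sicot 53 (-5.21 ± 0.36 and -5.54 ± 0.36), where its signals were 16.1 and 26.9. These values ranged from -6.44 to -3.89 at 32 °C and from -6.21 to -4.46 at 42 °C over pseudocounts of 1 to 64 and the other alternatives, so the folds of dim probe sets are not exact. The next at 32 °C was 22.2-fold lower (-4.47 ± 0.30). Of the 21 probe sets called at either temperature, 15 were called at both, and all 21 had the same sign at both. That holds for probe sets chosen by their calls: over all tested probe sets the differences at the 2 temperatures correlated at r = 0.178 (Spearman's rho = -0.008), a description across genes. In limma, 359 probe sets at 32 °C and 494 at 42 °C had an unadjusted p under 0.05, where chance gives 841. Most of these differences therefore cannot be told from noise, and the low r does not show that they change with temperature. None of the 21 passed the test of a difference between temperatures, in which every tested probe set had an adjusted p of 1. In 12 of the 21, the cultivar with less signal lay below the median of 100 of all values at both temperatures.

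Cell wall genes were lower in Sicot 53 as a list by camera with its preset correlation, and by no other list test. At 32 °C, 2 of the 24 probe sets had positive values, with a median log2 difference of -0.30 (camera adjusted p = 0.000692 with the preset correlation, adjusted p = 0.629 with an estimated correlation, and fry adjusted p = 0.915). A probe set of the expansin EXPA13D had the lowest p (-3.09 ± 0.67 SE, adjusted p = 0.33 over all genes), and 1 probe set passed when adjusted over the list alone. Another probe set named EXPA13D had -0.79 at 32 °C and +0.13 at 42 °C, so the large difference was not shared by both. XTH had -1.36 ± 0.77. At 42 °C, 8 of the 24 had positive values and the median was -0.23 (camera adjusted p = 0.0421, adjusted p = 0.463 with an estimated correlation, and fry adjusted p = 0.67). The first EXPA13D probe set had -2.75 ± 0.67 and the cellulose synthase CelA1 -0.93 ± 0.37. Ethylene genes were higher in Sicot 53 at 42 °C as a list by the same test alone, with a median of +0.12 that turned to -0.19 under scaling to the spikes, where the median of all tested probe sets was -0.31 (camera adjusted p = 0.0421, adjusted p = 0.463 with an estimated correlation, and fry adjusted p = 0.67). The ACC synthases ACS and ACS3 had +1.68 ± 0.53 and +1.14 ± 0.52, and 0 of the 8 probe sets passed on their own. Under that scaling the median of the cell wall list was -0.50 at 32 °C and -0.53 at 42 °C, against medians of all tested probe sets of -0.20 and -0.31, and 8 probe sets were called higher and 12 lower in Sicot 53 at 42 °C. RCA1 had a cultivar difference of +0.43 ± 0.28 at 32 °C and +0.02 ± 0.28 at 42 °C, where the highest values of the arrays had +0.36 and -0.01, and the sign of the latter turned under scaling to the spikes (-0.29). The ethylene list did not pass at 32 °C (camera adjusted p = 0.8), nor did the peroxidase and lipid lists at either temperature. The lipid list had a median of -0.07 and a mean of +0.06 at 32 °C.

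**Figure D4:**
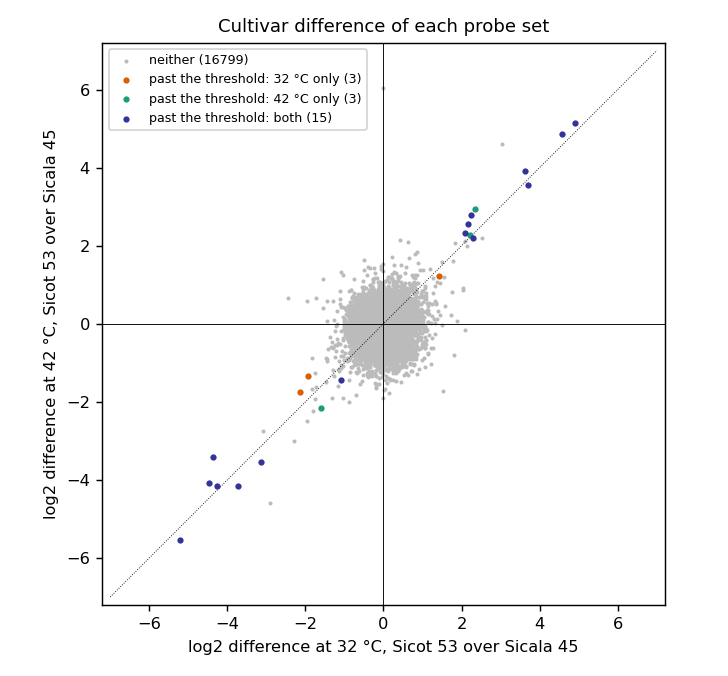
Log2 difference of Sicot 53 over Sicala 45 of each of the 16820 tested probe sets at 32 °C (x axis) and 42 °C (y axis), coloured by whether it passed the threshold at 1 temperature, both or neither, with a dotted line of equal difference. The 15 probe sets past the threshold at both temperatures lie near the line, from -5.21 to +4.90 at 32 °C, while all tested probe sets gave r = 0.178.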

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

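For the poly-A spikes, the tests of hybridisation, of a labelling batch and of less polyadenylated RNA were chosen after the result was seen, and the test of lost RNA before. Whether single arrays stand apart within their groups was not tested.

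Control probe sets outside the comparisons of genes gave a difference between temperatures. The poly-A spikes had 1.45 times the signal at 42 °C. The ubq11 3'/5' ratio was 2.25 times as high, and the ubq11 3' signal 1.76 times as high (log2 change +0.82 ± 0.19 SE, exact permutation p = 0.005).

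The rise of the spikes has several candidate explanations, and none is excluded. Stronger hybridisation of the 42 °C arrays could raise them only if uneven across probe sets, as scaling each array to the same trimmed mean removes an even rise. The hybridisation controls, added later, had a log2 change of 0.25 ± 0.31 SE, too imprecise to decide. Loss of intact RNA could do so too, and within groups the mean 3'/5' ratio and the spike level correlated at r = 0.37 (12 arrays, permutation p = 0.355; Spearman's rho = 0.35, permutation p = 0.385; r = 0.31 without the 2 farthest arrays), which leaves it open. A labelling batch that differed between cabinet runs, or a biological change, less polyadenylated RNA in leaves at 42 °C, both predict a rise in each cultivar, and the log2 change was 0.48 in Sicala 45 and 0.58 in Sicot 53. These 2 cannot be told apart, since temperature and cabinet run coincide.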

How the results depend on the processing

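Scaling to the spikes, the 3'/5' ratio as a covariate and leaving out the 2 arrays of high ubq11 ratio were chosen after the data were seen. Of 45 named values past the threshold, none turned sign under any alternative and 26 kept their calls under every one. Of the 109 named values not past it, 38 turned sign at least once, 22 under scaling to the spikes. No cause was tested except where the setting leaves fewer arrays or probe sets. Dim probe sets limit the folds, as there are no detection calls. Probe sets past the threshold changed as follows. Array weights gave 513 for heat in Sicala 45, 2000 in Sicot 53 (885 higher, 1115 lower), 2954 averaged, and 35 and 30 for the cultivars at 32 and 42 °C. Fitting only the groups compared gave 140 for Sicala 45 and 60 for Sicot 53. Scaling to the spikes gave 502, 622 and 5865 averaged, the last with 1036 of the 1481 kept. The 3'/5' covariate gave 149 for Sicot 53. Without the 2 arrays, 15 passed in Sicot 53 and 783 averaged. Leaving out single arrays gave 98 to 335 for Sicala 45, 18 to 276 for Sicot 53, 763 to 1681 averaged, 13 to 20 and 15 to 21 for the cultivars, and 0 to 1 for the difference between heat changes. The correlation of heat changes was 0.798 with the dimmest 50% left out, 0.571 with no filter on dim probe sets and 0.589 to 0.71 with single arrays left out.

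Of the gene lists, the 1 at 32 °C fell to 0 with an estimated correlation. The 2 at 42 °C became 0 with an estimated correlation, 1 probe set per gene name, a pseudocount of 64, the dimmest 50% left out or scaling to the spikes, and 1 with quantile normalization, median centring, no filter or only the groups compared.

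Signs turned in these values, none past the threshold. Those of RCA1, at 82.4% to 89.5% of each array's highest value, say little about its transcript level. RCA1 had -0.01 (quantile) and -0.16 (spikes) in Sicala 45, -0.04, -0.41 and, without Sicala 45 at 32 °C replicate 1, 0 averaged (0 to 0.24 over single arrays). In Sicot 53 it had 0.06 (median centring) and -0.30 to 0.02 over single arrays. Between cultivars at 42 °C it had -0.29 (spikes) and -0.06 (without the 2 arrays), and -0.05 to 0.16 over single arrays. Scaling to the spikes moved the median of all tested probe sets from -0.05 to -0.53 for averaged heat, so small positive values turn by that shift. With it, CLP had -0.21, GOX -0.26, CSD2a -0.26, Lea14-A -0.02 and E6 -0.31. Lea5-D had -0.33 with the covariate. CAT2 had 0.01 without the 2 arrays and -0.23 to 0.01 over single arrays.

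The replicate block gave 223 for Sicala 45, 165 for Sicot 53, 1316 averaged, 16 and 15 for the cultivars and 0 for the difference. Over all groups, 7 of 18 same-numbered pairs deviated together at r above 0.1, and 13 of 36 matches were best with the own number. These counts include pairs between temperatures, which join different cabinet runs. Between the cultivars at 1 temperature, same-numbered arrays had r of -0.12, 0.45 and 0.36 at 32 °C. At 42 °C they had 0.41, 0.39 and -0.16. Whether the numbers pair arrays within a run is therefore open.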

Other observations

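The gene families here were chosen after gene names and values were seen, as were the tests of 3' bias and of a batch by replicate number; the other tests here were chosen before. Of 8 probe sets of 5 NAC genes, 4 rose with averaged heat and 0 fell, where 709 of all 16820 tested probe sets rose. Those 4 are the probe sets of NAC4 and NAC2, and NAC5, NAC7 and NAC10 did not pass. When adjusted over the family alone, 5 passed. As NAC4 and NAC2 were among the largest named rises when the family was chosen, these counts are no test of the family. The median log2 change of the 8 was 1.09, with a range of 0.13 to 3.33. All 8 were positive as deposited, with quantile normalization and with median centring, and 6 were positive under scaling to the spikes (median 0.60, 4 called). Of 9 MAP kinase and MAP kinase kinase kinase probe sets, 1 fell, a dim one named MPK3 (-1.07 ± 0.30 SE, limma adjusted p = 0.0472, mean signal 36.4). The other probe sets of that name did not pass, at -0.33, -0.30, -0.63 and +0.13, so a fall of MPK3 rests on 1 probe set. None of 6 MYB, 3 WRKY or 8 tubulin probe sets passed.

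Within groups, 39.5% of the variance lay along 1 axis, on which Sicala 45 at 42 °C replicate 1 (-60.4) and Sicot 53 at 42 °C replicate 2 (53.5) stood at the ends. A batch by replicate number over all groups was predicted to make at least 12 of 18 same-numbered pairs deviate together, and 7 did. Pairs between temperatures join different cabinet runs, so a batch by number within a run stays open. A candidate explanation is 3' bias from RNA integrity or cDNA synthesis: the scores went with the mean 3'/5' ratio at r = 0.77 (12 arrays, permutation p = 0.0247, 0.0618 adjusted over 5 relations; Spearman's rho = 0.69, permutation p = 0.0741; r = 0.62 without the 2 farthest arrays). Unequal heat response among the 42 °C arrays, the biological explanation, stays open. The scores varied more at 42 °C, as it predicts (variance ratio 2.46, where at least 2 was predicted), while the loadings correlated with the heat change across probe sets at 0.10 with a jackknife SE of 0.39.

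The differences of the 21 called probe sets were of similar size at both temperatures, but these were chosen for large differences in the same data. The r of 0.178 over all tested probe sets is no contrast to this, since most of their differences cannot be told from noise. A swapped array is argued against: 0 arrays lay nearer to the other cultivar at most of the 13 or 14 probe sets called on the arrays of the other temperature. Sequence variants under the probes may contribute, and the 4 called probe sets with others of their cluster number left this undecided, at a median ratio of 0.26 (-0.01 to 0.59). A difference in expression between the cultivars stays open, untested.

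Other splits of the arrays were counted for each comparison. For averaged heat, 1481 probe sets passed and the highest of the other splits gave 14 (1 of 100 as large, the real one included). In the other splits the heat change adds to the spread within groups, which lowers their counts. The splits also cannot cover differences between cabinet runs, which coincide with temperature, so chance is not excluded by them. For the difference between heat changes the real value was 0 and the highest other 1792. Every split reaches a count of 0, so that all 100 were as large decides nothing. Of the other splits, 9 gave more than 0, which points to a structure of the samples. For heat in Sicala 45 (304), heat in Sicot 53 (228) and the cultivars at 32 °C (18), the highest other split gave 0, and 10 splits are too few for a share under 0.05. For the cultivars at 42 °C, with 18, another split gave 747, and 2 of 10 were as large. That split had Sicala 45 replicate 1 and Sicot 53 replicates 1 and 3 on one side, which points to a structure of the samples. It follows the main axis within groups: these arrays scored -60.4, -26.3 and -27.2 on it. The rest at 42 °C scored 33.5, 27 and 53.5.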
